A study of Homo sapiens with 4 samples.

How the data were processed

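HEK293T cells, a human embryonic kidney line that carries the SV40 large T antigen, were used for 4 libraries: RNA recovered with biotin-labelled miR-34a, RNA recovered with a control (labelled NC by the submitters), total RNA after a miR-34a mimic, and total RNA after a control mimic. miR-34a is a microRNA induced by p53, a mimic is a synthetic RNA duplex that supplies a microRNA to the cell, and a pulldown recovers RNA bound to the labelled microRNA on streptavidin. RNA was isolated with Trizol, per the labels' protocols. Each of the 4 groups has 1 library, so no difference below has a replicate check, and no p-value was computed.

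The deposited read counts are whole numbers per RefSeq transcript, made by the authors and not normalized. The authors also deposited an RPKM value beside each count. The submitters' processing notes name Bowtie2, edgeR and the genome build hg38; versions, roles, filters and strand handling are not given in the sources used here. The columns named NC and PD of the pulldown sheet were taken as the control and miR-34a pulldown libraries, and the columns named NC and mimic of the mimic sheet as the control and miR-34a mimic libraries. A pair of further deposited tables, named for the UTR, repeat rows of the full tables with the same counts and hold every listed transcript of 2880 pulldown genes and 4126 mimic genes. The criterion behind this UTR subset is not given in the sources used here; it was used only as a list of genes.

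Several properties of the values were checked on the deposited tables. The lowest control count in both tables is 1, so transcripts without a control read are not listed and enrichment of such transcripts was not analysed here. Among genes with 1 listed transcript and 2 to 9 reads, 96.0% of control and 96.3% of miR-34a counts in the mimic table were even, against 73.5% and 61.7% in the pulldown table. At 10 to 49 reads these were 81.9% and 83.6% in the mimic table and 52.3% and 51.0% in the pulldown table, where no excess is left. Counting a read pair as 2 reads would give such an excess. All counting intervals were computed on counts divided by 2, for which the support in the pulldown is limited to the lowest counts, and which lowers the number of genes called there. The RPKM worth of 1 read of a transcript was the same in the pulldown and mimic tables for all 16587 shared transcripts, and the miR-34a over control ratio of that worth was 0.6941 in both, whereas the control total over the miR-34a total was 0.5621 in the pulldown and 1.0659 with the mimic. The million-read factor is therefore not that of each library, and the RPKM columns were used only as an alternative scaling.

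Reads were summed over the transcripts of each gene name, and gene names that a spreadsheet had turned into dates were resolved through their accessions. Accessions were matched to the GRCh38.p14 RefSeq gene table for current symbols and gene positions (98.8% of pulldown and 98.3% of mimic transcripts matched). Library totals were 306996 reads for the control pulldown, 546180 for the miR-34a pulldown, 45493090 for the control mimic and 42679778 for the miR-34a mimic. Totals were scaled with TMM factors (edgeR 4.0.16 in R 4.3.3), and the log2 ratio of miR-34a over control was taken for genes with at least 20 reads in the 2 libraries together. A library at 0 was set to 3 reads per library, which gives the gene a place in the ranking, although a gene with 1 or 2 reads can then rank as more extreme than one with 0; the text gives the upper end of its interval instead of that ratio. The 95% interval of each ratio is the exact conditional binomial (Clopper-Pearson) interval (Python 3.11.15, scipy 1.17.1). A gene is called higher or lower beyond counting error where this interval excludes a ratio of 1. Such intervals cover counting error in these libraries only, not the variation between cultures or pulldowns.

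For each of 15 gene lists, and for the UTR subset, the median log2 ratio was placed among the medians of 10000 random lists of the same size, matched on mean expression in 10 bins and drawn from genes outside the list. A percentile below 2.5 or above 97.5 is called outside the random lists; it describes these libraries. The overlap of both approaches was compared with the product of the list sizes over the number of genes and with 10000 random lists of other genes matched on total RNA level. The Fisher p-value set in the design is not given, since genes are not replicates. Correlations are across genes. Genes were named by a rule: the 10 highest and 10 lowest ratios of each comparison, up to 12 published targets beyond counting error, the 12 overlap genes with the lowest mimic ratio, and the 3 members of each list farthest from 0; any other gene is said to have been named after its values were seen. Some genes that met the rule are not reported here. Lists, rule and the alternative settings were otherwise fixed before the data were examined. The halving, the 99% interval in place of a stricter p, the RPKM and library-total scalings, the limit to genes with every transcript listed, the 100-read limit and a list of 337 genes commonly carried by cancer sequencing panels were added afterwards. Counts were also simulated as read pairs of 2 reads with counting error alone, and called after halving. With 6278 pulldown genes, 49.5% of 99 doubled genes and 40.5% of 79 halved genes that kept 20 reads were called. Of unchanged genes 2.92% were called. With 14771 mimic genes these were 95.0% of 100, 88.9% of 99 and 4.28%. The pulldown counts showed no such pairing from 10 reads up, so the pulldown shares depend on that assumption.

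DESeq2 1.42.0 was used only for its size factors as an alternative scaling. The seed site comparison of the design was made with the UTR subset alone; site types and 3′ UTR lengths were not analysed here, because no sequence was used. The 15 lists were published miR-34a targets, growth factor signalling, G1/S and replication, mitosis (G2/M), p53 targets, silencing machinery, interferon response, Notch and Wnt, apoptosis, cytosolic ribosomal proteins, mitochondrially encoded genes, housekeeping genes, secretory pathway and ER stress, and markers of blood cells and fibroblasts.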

Results

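The series set 2 approaches to finding the RNAs that miR-34a acts on side by side in HEK293T cells: recovery of bound RNA with biotin-labelled miR-34a, and RNA sequencing after a miR-34a mimic. Each arm had its own control library, and each of the 4 groups had 1 library. The pulldown libraries held 306996 control and 546180 miR-34a reads over 10661 genes, with a median of 6 and 11 reads per transcript. The total RNA libraries held 45493090 control and 42679778 mimic reads over 16445 genes, with medians of 407 and 381 reads per transcript. A minimum of 20 reads left 6253 pulldown genes and 14784 mimic genes. All ratios below are miR-34a over control on the log2 scale, and brackets after a ratio give its 95% counting interval. They compare these libraries, with no replicate check. Gene positions are those of GRCh38.p14.

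The pulldown comparison asks which RNAs were recovered with miR-34a above the control. The highest ratios were those of TET2, FOXA1, PDGFRA and NOTCH4. TET2, a DNA demethylation enzyme on chromosome 4 (105145875 to 105279803), had 2 control and 145 miR-34a reads, a log2 ratio of 5.38 [2.86 to 10.71]. FOXA1, a pioneer transcription factor, followed at 5.18 [1.86 to 15.21], PDGFRA, a growth factor receptor, at 4.99 [1.65 to 15.02], and NOTCH4, a Notch receptor, at 4.89 [2.35 to 10.22]. ERCC5, a nucleotide excision repair nuclease, stood at 4.79, CNTNAP1, an axonal adhesion protein, at 4.66, and MAP3K1, a kinase of the MAPK cascade, at 4.33. SDHD, a subunit of succinate dehydrogenase, had 4.31, BRIP1, a helicase that binds BRCA1, 4.16, and ABCC4, an organic anion exporter, 4.11. Each of these 10 genes had 1 to 3 control reads, which is why the upper ends of their intervals are far from the ratios. Over all genes, 443 were higher and 229 lower than the control beyond counting error, and the median log2 ratio was 0.11. Without halving the counts for the intervals, 968 were higher and 587 lower. On the deposited RPKM scale the median was 0.38, with 893 genes higher and 89 lower. 8 of the 10 genes are on a list of 337 genes commonly carried by cancer sequencing panels, drawn up after the ratios were seen.

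The lowest pulldown ratios included genes with many reads in the control pulldown. LYSMD1, a LysM domain gene on chromosome 1, had 3918 control and 38 miR-34a reads, a log2 ratio of -7.48 [-8.22 to -6.84]. BHLHE22, a neuronal transcription factor, had 582 and 0 reads, which puts the upper end of its interval at -7.09. AVIL, an actin-binding protein of the villin family, had 948 and 22 reads, and C3orf38 had 180 and 3. VCL, which encodes the focal adhesion protein vinculin and is on the list of published targets, had 1326 and 131 reads, a log2 ratio of -4.14 [-4.52 to -3.77]. FAM84A, MAST1, ISPD and CEP85L lay between -6.12 and -4.60. The pseudogene WBP11P1, with 34 and 0 reads, had an upper end of -2.84; as a pseudogene it can share reads with its parent gene.

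Of 62 published miR-34a targets, 34 were measured in the pulldown. 5 were higher and 1 was lower beyond counting error, and the median log2 ratio of 0.16 lay at percentile 72.7 of matched random lists. The higher ones were PDGFRA, MYCN (4.09 [1.5 to 9.44]), the hepatocyte growth factor receptor MET (2.22 [0.88 to 3.92]; chromosome 7, 116672196 to 116798377), NOTCH1 (1.25 [0.74 to 1.79]) and NOTCH2 (0.82 [0.42 to 1.24]). All 5 are also on the cancer panel list, of which 243 genes were measured with a median log2 ratio of 0.95, against 0.09 for other genes. Without panel genes, 0 of 21 published targets were higher beyond counting error. Of all measured genes 7.08% were higher, and of genes off the panel list 5.44%. At that share a count of 0 among so few genes, here and in the lists below, decides little. The panel list was drawn up after the ratios were seen, so results without panel genes, here and below, are not an independent check. The lower gene was VCL.

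Growth factor signalling genes stood high as a group in the pulldown. 10 of 28 measured members were higher and 0 lower, and the median of 0.77 lay above the random lists (percentile 100, random range -0.18 to 0.36). Examples are PDGFRA, the receptor ERBB3 (3.99 [1.39 to 9.34]) and the lipid kinase subunit PIK3CA (3.88 [1.27 to 9.23]). 23 of the 28 members are on the cancer panel list; the other 5 had a median of 0.37 (percentile 78.1), and 0 of them were higher beyond counting error. Cytosolic ribosomal protein genes were also high: 54 of 78 were higher and 0 lower, with a median of 0.43 (percentile 100), and 0 of them are on the panel list. RPS24 reached 1.47 [0.99 to 1.98], RPL26 1.19 and RPL17 1.06; these genes have processed pseudogenes that can share reads. The list median was 0.39 on library totals, 0.41 on DESeq2 size factors and 0.70 on deposited RPKM.

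The other lists lay within the random lists in the pulldown. Notch and Wnt genes had 6 of 22 members higher, among them NOTCH3 (3.86), the β-catenin scaffold AXIN2 (2.60) and APC (2.11), with a median of 0.14 (percentile 66.8); 8 of the 22 are panel genes, and 0 of the other 14 were higher. Among genes above the median expression the list was outside the random range, at 0.70 (percentile 100); against random lists not matched on expression it was at percentile 58.5. G1/S and replication genes had 3 of 36 higher, CCNE1 at 1.82, CDK2 at 1.20 and CCND3 at 1.18, and 1 lower, MCM2 at -0.44 (median 0.20, percentile 86.9). Mitotic genes had 2 of 28 higher, BUB1 at 1.60 and PLK1 at 0.97 (median 0.25, percentile 90.5). p53 targets had XPC at 1.53 and MDM2 at 1.31 higher and FDXR at -1.97 lower among 15 (percentile 69.4). Of 16 silencing machinery genes, DICER1, the nuclease that matures microRNAs, was higher at 1.31 (percentile 55.2). DICER1, CCNE1, CCND3 and MDM2 are panel genes. Without panel genes, 0 of 15 silencing machinery genes, 1 of 29 G1/S and replication genes and 1 of 11 p53 targets were higher. Interferon response genes (6 measured, percentile 47.0) and apoptosis genes (13 measured, percentile 46.7) had 0 members beyond counting error. Secretory pathway genes had 1 of 14 higher, XBP1 at 0.91, and 1 lower, CALR at -0.49 (percentile 58.9). Housekeeping genes had 1 of 22 higher, EEF1A1 at 0.23, which has many pseudogenes, and 1 lower (percentile 92.8). MCM2, CALR and EEF1A1 were named after their values were seen. Of the fibroblast markers 4 were measured, PDGFRA being higher (percentile 52.6). 0 blood cell markers reached 20 reads, and 0 of the 13 mitochondrially encoded genes were measured in either comparison.

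**Figure D1:**
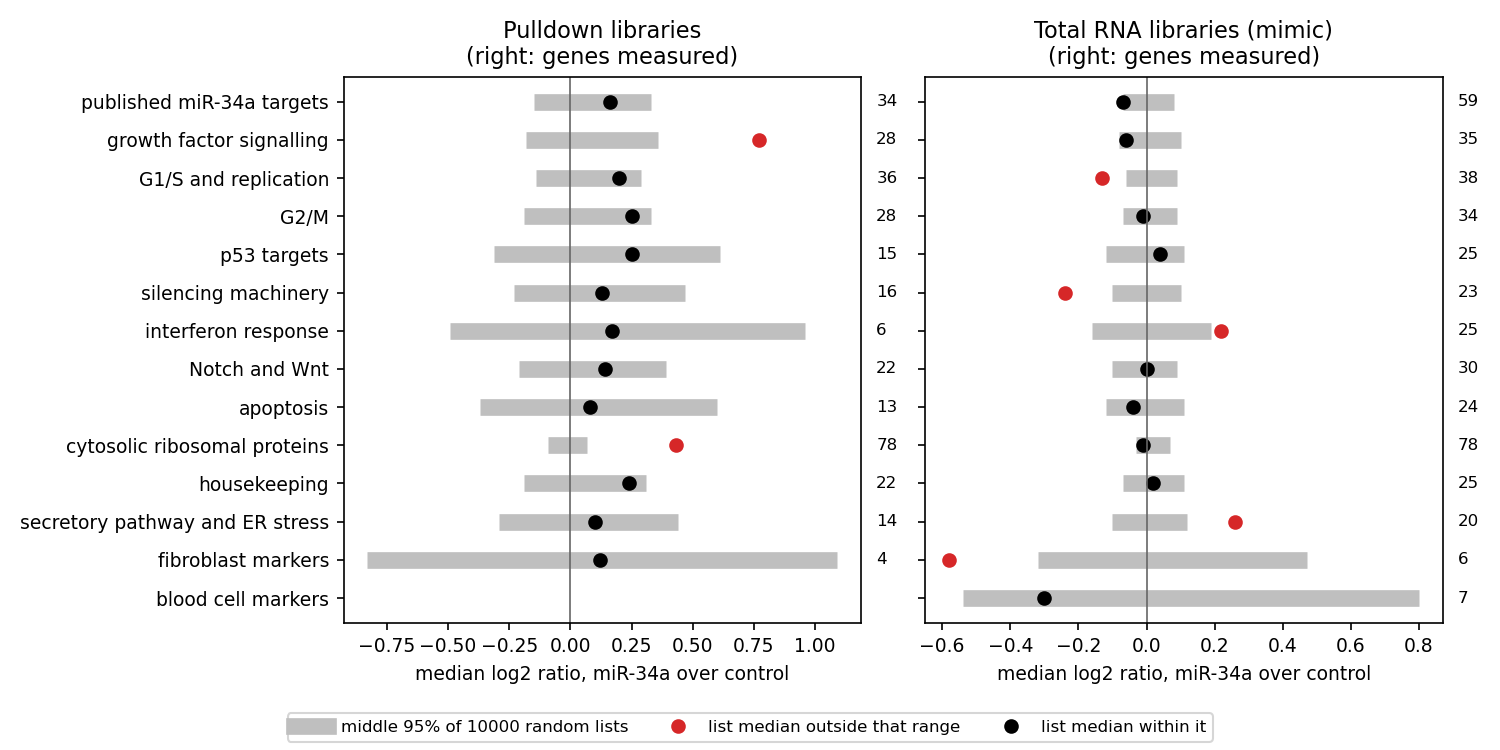
Median log2 ratio (miR-34a over control) of each gene list in the pulldown libraries (left) and the total RNA libraries (right); points are medians, red where outside the middle 95% of matched random lists, grey bars are that range, and numbers at the right are genes measured. Growth factor signalling (0.77) and ribosomal protein genes (0.43) lie above the range in the pulldown, and silencing machinery (-0.24) and G1/S genes (-0.13) below it with the mimic, where deposited RPKM would shift every list alike to below 0.

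The mimic comparison asks which RNAs differ in level once miR-34a is supplied. The highest ratio was that of MMP1, interstitial collagenase (chromosome 11, 102789919 to 102798160), with 13 control and 1704 mimic reads, a log2 ratio of 7.15 [6.06 to 8.53]. The sperm calcium channel gene CATSPER1 had 2 and 60 reads (5.02), and the trypsin inhibitor SPINK1 2 and 36 (4.29). The cytokine IL11 had 26 and 283 reads (3.56 [2.74 to 4.51]) and the stromelysin MMP10 had 10 and 108 (3.55 [2.24 to 5.23]). BHLHE23 (3.92), CYP24A1 (3.82), C1QTNF8 (3.58), SDR16C5 (3.58) and ABI3 (3.51) completed the 10 highest, each with 2 or 4 control reads. Among the lowest was IRS4, an insulin receptor substrate, with 887 and 14 reads (-5.87 [-7.19 to -4.81]; chromosome X, 108719946 to 108736563). The nucleotide synthesis gene CTPS2 had 98 and 2 reads (-5.50), TENM1 92 and 2 (-5.41), GPR50 71 and 2 (-5.03), PPP1R14A 62 and 2 (-4.84), NAP1L2 46 and 2 (-4.41) and PRDM13 28 and 2 (-3.69). ELAVL2, with 46 and 0 reads, and CTSF, with 40 and 0, had intervals with upper ends at -2.41 and -2.19.

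Beyond counting error, 3740 genes were higher and 3412 lower with the mimic, and 487 and 153 of these also differed by at least 2-fold. The quartiles of the log2 ratios were -0.18 and 0.21. The median log2 ratio over all genes was 0.00 with TMM scaling and -0.65 on the deposited RPKM scale, on which 365 genes were higher and 11731 lower. Directions below are relative to the median gene. Deposited RPKM moves all ratios of a comparison alike, so a change of sign on that scale restates the shift and leaves the order of genes as it is.

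Published targets went both ways with the mimic. Of 59 measured, 21 were lower and 19 higher beyond counting error, and the median of -0.07 lay at percentile 2.76. It was at 1.8 among genes above the median expression and at 5.85 of random lists not matched on expression. PDGFRA was lower at -1.11 [-1.87 to -0.39], the cyclin CCNE2 at -0.62 [-0.81 to -0.43], MET at -0.45 [-0.60 to -0.31] and the transcription factor E2F3 at -0.34 [-0.42 to -0.25]. MYCN (2.60 [1.42 to 4.0]), the interleukin 6 receptor gene IL6R (1.63 [1.45 to 1.81]), PDGFRB (1.37), CEBPB (1.29), the AP-1 subunit FOSL1 (1.13), the hyaluronan receptor CD44 (1.04 [0.94 to 1.14]), SNAI1 (1.01), AXL (0.75), ULBP2 (0.71) and RRAS (0.62) were higher.

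Silencing machinery genes were lower as a group, with 17 of 23 lower and 2 higher and a median of -0.24 (percentile 0.0, random range -0.10 to 0.10). PAN2, a deadenylase subunit, was at -0.51 [-0.63 to -0.40], the deadenylase CNOT6 at -0.46 and the decapping enzyme DCP2 at -0.43. The Argonaute genes AGO2 (0.33) and AGO4 (0.26) were the 2 higher, and lay at -0.32 and -0.39 on deposited RPKM. G1/S and replication genes were also lower: 22 of 38 lower, 5 higher, median -0.13 (percentile 0.0), with CCNE2 and E2F3 as examples. The 5 higher were CCND1, UHRF1, CCND3, CDK4 and TK1, between 0.06 and 0.25, and all 5 lay below 0 on deposited RPKM. Secretory pathway and ER stress genes were higher, 15 of 20 against 1 lower (SEL1L, -0.24), with a median of 0.26 (percentile 100), which was -0.38 on deposited RPKM, where the median gene was at -0.65. TRIB3, a pseudokinase of the stress response, was at 1.33 [1.17 to 1.5], CHAC1 at 0.94 and XBP1 at 0.64; on deposited RPKM XBP1 was at -0.01. Interferon response genes had 9 of 25 higher and 5 lower, with a median of 0.22 (percentile 98.7), or -0.42 on deposited RPKM. The bootstrap interval of that median, -0.23 to 0.37, holds 0. BST2 was higher at 1.23 and MX1 lower at -1.07, with IRF9, IRF7, USP18 and STAT2 the other lower genes. RSAD2 was at -0.88 [-2.43 to 0.52]. Among genes above the median expression the interferon list was within the random range (percentile 95.7), and against random lists not matched on expression it was at percentile 99.8. Fibroblast markers had a median of -0.58 (percentile 0.04), with a bootstrap interval of -0.89 to 1.4 that holds 0. Of 6 measured, PDGFRA, LUM (-0.67), COL3A1 and FBN1 were lower and THY1 (2.34) and COL1A1 (0.47, or -0.17 on deposited RPKM) higher. Members of these lists beyond the 3 farthest from 0 were named after their values were seen.

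The remaining lists lay within the random lists with the mimic. Growth factor signalling genes had 13 higher and 13 lower of 35 (percentile 7.47), mitotic genes 10 and 11 of 34 (percentile 36.6) and p53 targets 9 and 10 of 25 (percentile 80.4). Among mitotic genes CDC25B (0.59), CENPA (0.40) and BUB1 (0.28) were higher, all 3 below 0 on deposited RPKM. Among p53 targets GDF15 (1.28), PHLDA3 (0.99) and GADD45A (0.77) were higher. Notch and Wnt genes had 11 higher and 12 lower of 30 (percentile 57.6), with NOTCH3 at 1.02, DLL3 at 0.96 and WNT5A at -0.79. Apoptosis genes had 5 higher and 8 lower of 24 (percentile 33.4), with BIK at 1.07 and BCL2L11 and CASP9 at -0.50; the other higher genes were BAX, BAD, BCL2L2 and BAK1, all 4 below 0 on deposited RPKM. Ribosomal protein genes had 27 higher and 34 lower of 78 (median -0.01, percentile 10.4), and housekeeping genes 12 and 8 of 25 (percentile 55.7), with TFRC at 0.54, or -0.11 on deposited RPKM, and TBP at -0.22. Blood cell markers had 2 higher and 2 lower of 7 (percentile 12.7), with LCP1 at 1.70 against HBA1 at -1.42 and HBA2 at -1.41. Against random lists not matched on expression these markers were at percentile 0.905, outside. HBA1 and HBA2 are near-identical copies, and their counts are uncertain. BAX, BAD, BCL2L2, BAK1 and HBA2 were named after their values were seen.

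The UTR subset held 78.0% of the measured published targets, 46 of 59, against 25.8% of all measured genes. Its members lay within the random lists in both comparisons. In the pulldown the median log2 ratio was 0.08 for 1697 genes in the subset and 0.11 for 4556 outside, a difference of -0.03 (95% bootstrap interval -0.07 to 0.02, percentile 2.88). Without cancer panel genes it was -0.05 (percentile 1.16), outside the random lists, and among genes above the median expression 0.00 (percentile 68.6). With the mimic the difference between 3810 and 10974 genes was 0.00 (-0.01 to 0.02, percentile 96.8), and among genes above the median expression -0.01 (percentile 7.93). Genes higher in the pulldown made up 7.72% of the subset and 6.85% of the rest, and genes lower with the mimic 23.6% and 22.9%.

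**Figure D2:**
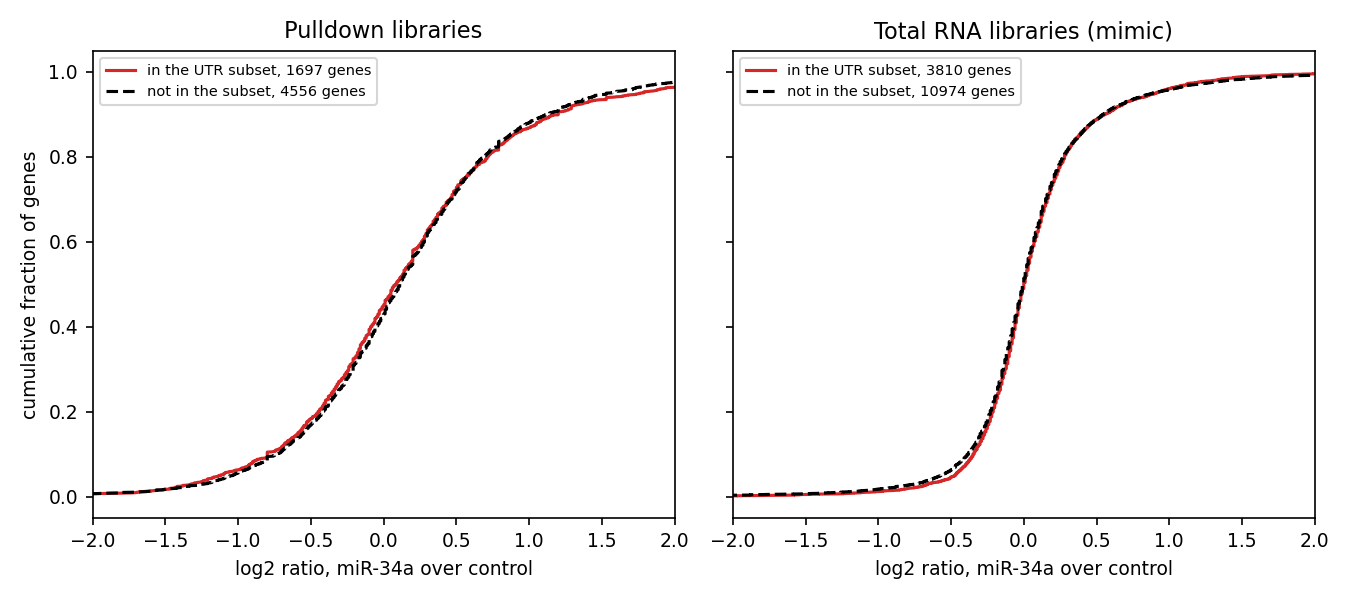
Cumulative fraction of genes (vertical axis) against the log2 ratio of miR-34a over control (horizontal axis, shown from -2 to 2) for genes in the UTR subset (red, solid) and outside it (black, dashed), in the pulldown (left) and mimic (right) comparisons. The paired curves nearly coincide, with median differences of -0.03 and 0.00.

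The series title sets the approaches against each other, so genes higher in the pulldown were compared with genes lower with the mimic. Of 6239 genes measured in both, 441 were higher in the pulldown, 1860 lower with the mimic and 173 both, against 131 for independent lists and 116 to 151 in 95% of random lists matched on total RNA level. The odds ratio was 1.57. The overlap genes with the lowest mimic ratio were PDGFRA (4.99 and -1.11), SPEN, a transcriptional repressor (0.69 [0.39 to 1.01] in the pulldown and -0.70 [-0.74 to -0.66] with the mimic), the kinase FLT3 (2.90 and -0.68), HIST1H2BD (0.63 and -0.66), the repair gene BRCA2 (2.99 and -0.65), SOX9 (1.68 and -0.56), CBX5 (1.19 and -0.51), ATAD5 (3.66 and -0.51), FAM46C (3.60 and -0.51), TERT (3.06 and -0.49), BRIP1 (4.16 and -0.47) and MET (2.22 and -0.45). HIST1H2BD shares sequence with other histone genes, and its counts are uncertain. PDGFRA, FLT3, ATAD5, FAM46C, TERT and BRIP1 had 1 or 2 control pulldown reads. The pulldown intervals of ATAD5, FLT3 and CBX5 began at 0.16, 0.17 and 0.19. Of the overlap genes named, PDGFRA, SPEN, FLT3, BRCA2, SOX9, FAM46C, TERT, BRIP1 and MET are on the cancer panel list. Without cancer panel genes 110 genes were in both sets, against 95.3 for independent lists and a random range of 85 to 116. That list was drawn up after the pulldown ratios were seen, so its removal can lower the overlap by the way it was made. With at least 2-fold in each comparison 1 gene was in both sets, PDGFRA, against 1.06 for independent lists. Across genes, the log2 ratios of both comparisons had a Pearson r of -0.03 and a Spearman rho of -0.05; genes are not independent replicates.

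**Figure D3:**
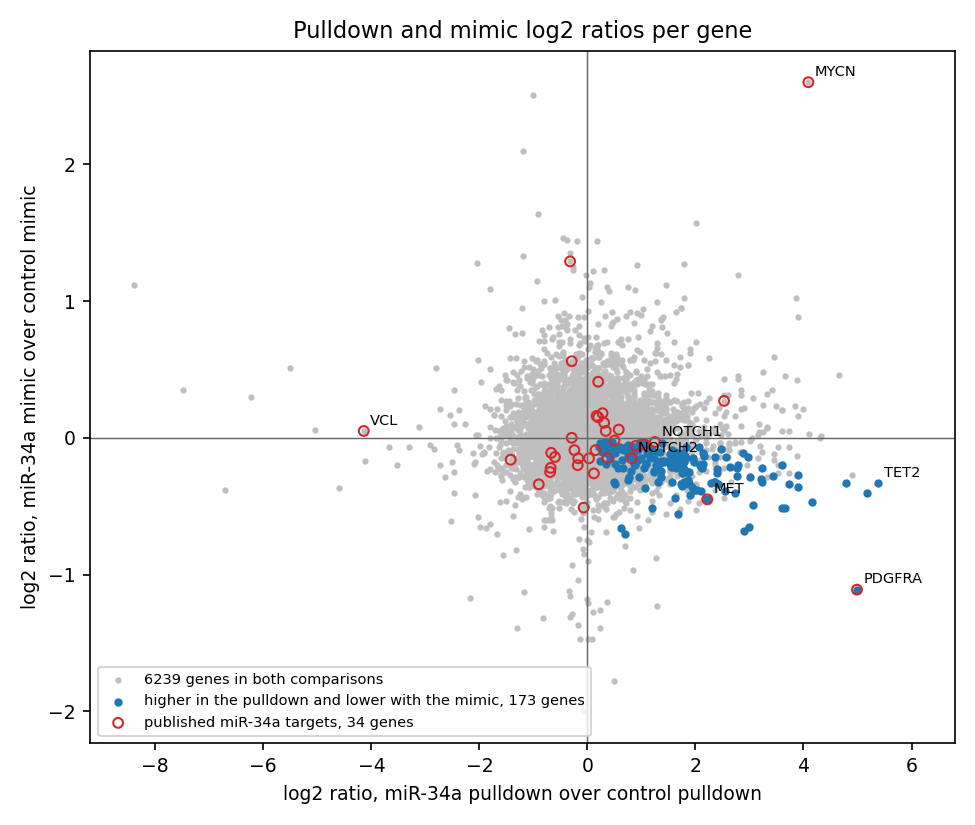
Log2 ratio with the mimic (vertical axis) against log2 ratio in the pulldown (horizontal axis) for 6239 genes (grey), the 173 genes higher in the pulldown and lower with the mimic (blue) and the published targets measured in both (red circles). Pearson r was -0.03, MET and PDGFRA lie at the lower right, and MYCN at the upper right.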

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

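The limits are 1 library per group and low pulldown counts. With 1 library, leaving out a replicate, a DESeq2 test and adjustment over a list alone could not be run. With pulldown counts simulated as read pairs and halved, a doubled gene was called in 49.5% of cases. That share reflects the assumed pairing as well as the low counts. No paired analysis was possible because each group has 1 library. Alternatives by site type and 3′ UTR length were not run, and no pseudocount was added to counts above 0; counts of 0 were set to 3 reads, for which no alternative was run; the 99% interval, halving, RPKM, library totals, 100-read limit, listed-transcript limit and panel alternatives were chosen after seeing the data. DESeq2 size factors, library totals and no filter on low counts kept each count of higher and lower genes within 1.5 times its value. The limit to genes with every transcript listed, run for the pulldown alone, left 408 higher and 214 lower. A 99% interval gave 228 higher and 107 lower pulldown genes, and a log2 minimum of 1 left 133 lower pulldown genes and 487 higher and 153 lower mimic genes, as stricter limits must. Counts not halved gave 968 higher and 587 lower pulldown genes. On the deposited RPKM scale there were 893 higher and 89 lower pulldown genes, and 365 higher and 11731 lower mimic genes; the read factor of those columns shifts all ratios of a comparison alike. On that scale B2M (-0.42), BUB1 (-0.36), CDC25B (-0.05), CENPA (-0.25), RPS7 (-0.43), RRAS (-0.02), TFRC (-0.11) and XBP1 (-0.01) changed sign with the mimic, which restates that shift, since each still lies above the median gene at -0.65. The odds ratio of the overlap fell to 0.943 with a log2 minimum of 1 in both comparisons, where 1 gene was left, and to 1.25 without panel genes, within the random lists. With panel genes kept, the overlap stayed above the random lists in the other settings. Its odds ratio was 2.05 with the 99% interval and 1.85 among genes above the median expression. It was 1.31 for the 500 highest pulldown ratios and 1.82 with 100 or more pulldown reads. Without panel genes 1 pulldown list (ribosomal proteins) stayed outside the random lists, and the UTR subset difference was -0.05 (percentile 1.16). The correlation was -0.08 among genes with 100 or more pulldown reads; the cause was not tested.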

Other observations

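The gene families and HMOX1 in this paragraph were chosen after their values were seen, the families from symbol stems with 15 or more measured genes. With the mimic 15 of 78 families lay outside the middle 95% of matched random lists, and in the pulldown 7 of 35. Chance alone leaves about 5% outside. Symbol families thus fell outside more often than random lists in both comparisons, a limit that may also hold for the gene lists above. Matrix metalloproteinase genes, which degrade extracellular matrix, had 11 of 16 higher and 0 lower with the mimic (median 0.59, percentile 100), MMP1 among them; on deposited RPKM this median was -0.06, where the median gene was at -0.65. Dual-specificity phosphatase genes, many of which switch off MAP kinases, had 13 of 22 higher and 2 lower (median 0.27, or -0.37 on deposited RPKM), and KLF transcription factor genes 8 of 15 higher and 1 lower (median 0.35, or -0.29). HMOX1, the haem-degrading enzyme, had 1076 control and 5659 mimic reads, a log2 ratio of 2.51 [2.38 to 2.65]. Zinc finger genes named ZNF had 131 of 490 lower and 34 higher (median -0.12), and USP deubiquitinase genes 26 of 50 lower and 4 higher (median -0.14). HIST1 histone genes had 9 of 30 lower and 0 higher (median -0.47); their near-identical copies make single counts uncertain. Among genes with 100 or more reads, chromosome medians with the mimic ran from -0.13 on chromosome 13 to 0.14 on chromosome 19.

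All tests of the patterns in this and the next paragraphs were chosen after the pattern, or values of its genes, had been seen. Cancer panel genes were high in the miR-34a pulldown: 116 of 243 measured (47.7%) were higher and 1 lower, against 5.44% of other genes higher. Low control counts as the whole cause are argued against, since 117 panel genes with 20 or more control reads had a median of 0.52 against a random range of -0.10 to 0.10. That median is below the 0.95 of all measured panel genes, so a part played by low control counts stays open. Binding at sites marked by the UTR subset stays open, since panel genes inside it were higher by 0.37 with an interval from -0.13 to 1.06. Reads from a cancer gene capture library are a candidate source: of 28 panel genes under 1 CPM in both total RNA libraries, 4 (14.3%, exact interval 4.03 to 32.7) had 10 or more miR-34a pulldown reads, against 1.06% (0.722 to 1.5) of 2923 other such genes and 0 to 2 in random lists matched on total RNA reads. Among them were KDR, PRDM1 and BTK, with 77, 38 and 24 miR-34a pulldown reads against 6, 2 and 2 in the control pulldown. KDR had 26 and 28 reads in the total RNA libraries. The hypothesis rests on 4 genes and on tables from which transcripts without control reads are absent. Its list is not given by the study and was drawn up after the ratios were seen. Recovery by miR-34a could give the same share, so the share does not tell these explanations apart. Recovery of these RNAs by miR-34a itself stays open. With the mimic, 121 of 307 panel genes were lower and 65 higher, with a median of -0.06 (percentile 0.01, random range -0.03 to 0.03). This goes with such recovery and is not expected from capture library reads in the pulldown, though an indirect effect of the mimic could also give it. It is weak support, since families not high in the pulldown were lower still with the mimic. ZNF genes were at -0.12 with the mimic (pulldown percentile 16.4) and USP genes at -0.14 (pulldown percentile 29.4), while other families, such as KLF genes at 0.35, were higher.

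The 10 lowest pulldown genes may owe their ratios to extra reads in the control pulldown. Over their level in the control mimic total RNA, the control pulldown had a median log2 ratio of 6.77 (bootstrap interval 4.35 to 9.30), where all genes had a median of -0.13 and 2.5% of them exceeded 1.89. All 10 lay above that level. These genes were chosen for many control and few miR-34a reads, and the same control reads enter this ratio. Selection alone can put a gene with little total RNA above 1.89. For AVIL, BHLHE22, CEP85L, FAM84A, ISPD, MAST1 and WBP11P1, at 0.176 to 15.5 CPM in control mimic total RNA, the comparison decides nothing. VCL, LYSMD1 and C3orf38 had 257, 29.9 and 28.4 CPM, where the read minimum alone does not force such a value. For these genes, a loss from the miR-34a pulldown of transcripts that the control held at their total RNA level is argued against. In the miR-34a pulldown the median over total RNA was 0.56 (bootstrap interval -1.08 to 3.57), where all genes had -0.08. BHLHE22 and WBP11P1 had 0 miR-34a reads, and setting these to 3 gave them the highest values, 4.38 and 4.97. Others had few reads, so this median cannot decide on a loss for the 10 genes as a set. A loss in addition to the extra reads stays open, also for single genes such as C3orf38 at -2.37. Whether the control sequence bound these transcripts was not tested.

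With the mimic, 14 genes had a log2 ratio of -3 or lower, 0 reads being set to 3. Of the 14, 1 (7.14%, exact interval 0.181 to 33.9) is in the UTR subset, against 78.0% of published targets. The 25.8% of all measured genes lies within that interval. The interval lies below the share of published targets, but a gene outside the subset lacks a site marked by it by definition. The share therefore cannot decide on direct repression of these genes. Whether the subset marks miR-34a sites is not known, and with the mimic the medians inside and outside the subset differed by 0.00. 8 of the 14 (57.1%, interval 28.9 to 82.3) lie on chromosome X, which holds 3.60% of measured genes, while the median of 530 X genes was 0.03. A culture or clone difference between the libraries that involves chromosome X is a candidate explanation. An indirect effect of the mimic stays open, as untested.

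The RPKM worth of 1 read was the same in the pulldown and mimic tables, so that ratios of the RPKM columns differ from those on library totals by 0.30 in the pulldown and -0.62 with the mimic on the log2 scale.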
